A study of Mus musculus with 14 samples.

How the data were processed

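The samples were monocytes isolated from the bone marrow of the legs of mice with a monocyte isolation kit (90 to 95% pure by flow cytometry, per the labels). They were cultured for 3 h with or without 20 ng/mL of mouse IL-4. Libraries were made from 500 ng of RNA with a stranded mRNA kit and sequenced as paired 100-nt reads on a NovaSeq instrument. The deposited values are raw counts per gene, 1 column per library. The labels name FastQC, STAR and the mm10 build, without versions or roles. The program that counted reads, the annotation release, the strand setting and any filters are not given in the sources used here. Whether the replicates are animals or pools is likewise not given. The column totals ran from 33432502 to 42885079, and all values were whole numbers from 0.

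Of the 55487 gene identifiers, 55094 matched the GENCODE M21 annotation of GRCm38 with their version and 55394 without it, which gave symbols and positions. In all, 27900 had 0 counts in every library. All 14 columns matched a sample. Groups came from the sample titles, which name genotype and treatment, and from the series design. Titles carry a number, and libraries of the same number paired. After group means were removed, the 2 libraries of a number correlated across 10660 genes at r of 0.326 to 0.679, and in 7 of 7 pairs each library matched its own number best. The numbers were therefore used as a block in an alternative model of the IL-4 responses and the interaction. No number occurs in both genotypes, so a fixed block cannot be applied to the genotype comparisons.

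Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups with default settings (14754 genes, holding at least 99.95% of each library's counts), and libraries were scaled by TMM. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 14 libraries (10 residual degrees of freedom), and contrasts were tested by the quasi-likelihood F-test. These were the IL-4 response in wild type, the IL-4 response in AhR-deficient, the genotype difference in medium, the genotype difference in IL-4, and the genotype by IL-4 interaction. P-values were adjusted by Benjamini-Hochberg over the genes kept, with calls at an adjusted p under 0.05. The standard error of a fold change is its size divided by the square root of F, and CPM values are TMM-scaled. Between replicates the counts spread more than counting error allows (chi-square per degree of freedom of 13.8 to 60.0 over pairs of replicates), so errors come from the replicates. Floors of 3 counts and exact intervals cover counting error only.

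The lists of genes, 31 of which were tested, covered IL-4 and AhR biology, metabolism, stress, monocyte and macrophage states and markers of other bone marrow cells. They were tested by camera (limma 3.58.1) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Beside it stood camera with an estimated correlation and fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes. Members were counted by their p adjusted over all genes and adjusted over the list alone. In the overlap of the IL-4 responses, expected counts are the product of the numbers of calls divided by the number of genes. Genes flanking Ahr were compared with the other autosomal genes by Fisher's exact test, two-sided. A sex-linked list served as a check of the samples.

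Genes were named by a rule: Ahr in every comparison, and, among called genes with a mean log2 CPM of 1 or more, a symbol that is not a placeholder and no overlap between the libraries of the groups, the 12 largest rises and the 12 largest falls. In each list described, up to 4 members with the smallest adjusted p were open to naming. A few single-gene results reached by the rule are not reported here. Where no gene was called, the 5 with the smallest p were named as failing. The comparisons, tests, lists, naming rule and first set of alternatives were fixed before the data were examined. Ahrr in the IL-4 responses, Fos, Fosl2, Sik1 and Sesn2 in the IL-4 responses with the block, Prg2 and the genes of the last part on metabolism, adhesion, dendritic cells and macrophages were chosen after their values were seen.

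Alternatives were other scaling (DESeq2 size factors or upper quartile in edgeR), other tests (DESeq2 1.42.0 Wald test, limma-voom), and no filter or a filter of 1 CPM in 3 libraries. Others were only the groups compared in the model, the numbers as a fixed or random block, each library left out in turn, and flanks of 5 and 40 Mb. Alternatives chosen after seeing the data were leaving out numbers 1 and 2, a granulocyte marker score (mean log2 CPM of the neutrophil and eosinophil lists) as covariate, counts on autosomes alone, and the block with limma-voom or DESeq2 for the interaction. Figures were drawn with matplotlib.

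The steps were tested on simulated counts with the dispersions of the data. Each gene had its mean over all 14 libraries in every group, apart from the changes put in. Of 67 genes changed 2-fold, 54 (80.6%) were recovered for the IL-4 response in wild type (14503 genes tested), 43 (64.2%) for the IL-4 response in AhR-deficient (14492 genes) and 46 (68.7%) for the genotype difference in medium (14513 genes). The numbers were 55 (82.1%) for the genotype difference in IL-4 (14488 genes) and 39 (58.2%) for the interaction (14502 genes), with 3 to 8 false calls. In each comparison the simulated list that changed was called, and 0 of 20 unchanged lists were. The simulated genes were drawn independently, so this cannot show how the preset correlation performs on lists of correlated genes.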

Results

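Messenger RNA was sequenced from monocytes isolated from the bone marrow of wild-type mice and of mice described as deficient for the aryl hydrocarbon receptor (AhR). AhR is a transcription factor activated by small ligands. The cells were cultured for 3 h in medium alone or with 20 ng/mL of IL-4, a cytokine known to drive alternative activation of monocytes and macrophages. The 14 libraries formed 4 groups. There were wild type in medium and wild type in IL-4 (n = 4 each, numbers 1, 2, 3 and 7). The others were AhR-deficient in medium and AhR-deficient in IL-4 (n = 3 each, numbers 4, 5 and 6). "AhR-deficient" is the label of the libraries throughout. In number order, the total counts were 33432502, 35940604, 41452854 and 35755833 for wild type in medium. They were 38033192, 42885079, 37906548 and 34689442 for wild type in IL-4. For AhR-deficient cells they were 38046199, 39377257 and 37850295 in medium and 35040003, 39940475 and 39726774 in IL-4. Of 55487 gene entries, 14754 had enough counts to be tested. The first 3 principal components held 62.2%, 19.6% and 5.1% of the variance. Fold changes are log2 values with their standard error (± SE) from edgeR. Levels are CPM (counts scaled to a common library size, mean ± SD over the libraries of a group), and p-values are adjusted over all genes tested.

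Ahr itself was expressed in every library and was higher, not lower, in the libraries labelled AhR-deficient. The gene (ENSMUSG00000019256.17, GRCm38 chromosome 12, 35497974 to 35535038, minus strand) stood at 13.02 ± 1.60 CPM in wild type and 20.9 ± 5.23 CPM in AhR-deficient cells in medium (log2 difference 0.69 ± 0.14, adjusted p = 0.0144). In IL-4 it stood at 25.5 ± 1.40 and 41.9 ± 4.43 CPM (log2 difference 0.71 ± 0.14, adjusted p = 0.0270). The groups did not overlap in either condition, which chance gives for 5.71% of genes at these group sizes. IL-4 raised Ahr in both genotypes, by 0.97 ± 0.13 in wild type (adjusted p = 5.05e-05) and 1.0 ± 0.15 in AhR-deficient cells (adjusted p = 1.54e-04). Ahrr, which encodes the repressor of AhR and is a known AhR target, was lower in AhR-deficient cells in IL-4 (-0.89 ± 0.20, adjusted p = 0.0438; 8.29 ± 1.45 against 15.3 ± 2.47 CPM). Ahrr passed there in 1 of 7 fits without 1 library (log2 differences of -0.98 to -0.75), and in medium its difference did not pass (-0.42 ± 0.20, adjusted p = 0.212). Ahrr rose with IL-4 in wild type (1.01 ± 0.18, adjusted p = 5.99e-04). Its change in AhR-deficient cells did not pass (0.54 ± 0.22, adjusted p = 0.0802; adjusted p = 0.0138 with the numbers as a block). The difference between these changes did not pass either (-0.47 ± 0.28, adjusted p = 1). The counts are per gene, so a deleted exon of Ahr could not be seen. The higher Ahr level missed the threshold in medium without AhR-deficient number 4 (log2 difference 0.49, adjusted p = 0.0889). In IL-4 it missed it without wild-type number 1, 2 or 7 (adjusted p = 0.0767, 0.0798 and 0.0526) and without AhR-deficient number 4 or 5 (adjusted p = 0.132 and 0.117). The log2 differences in IL-4 were 0.66 to 0.80 over all 7 such fits.

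**Figure D1:**
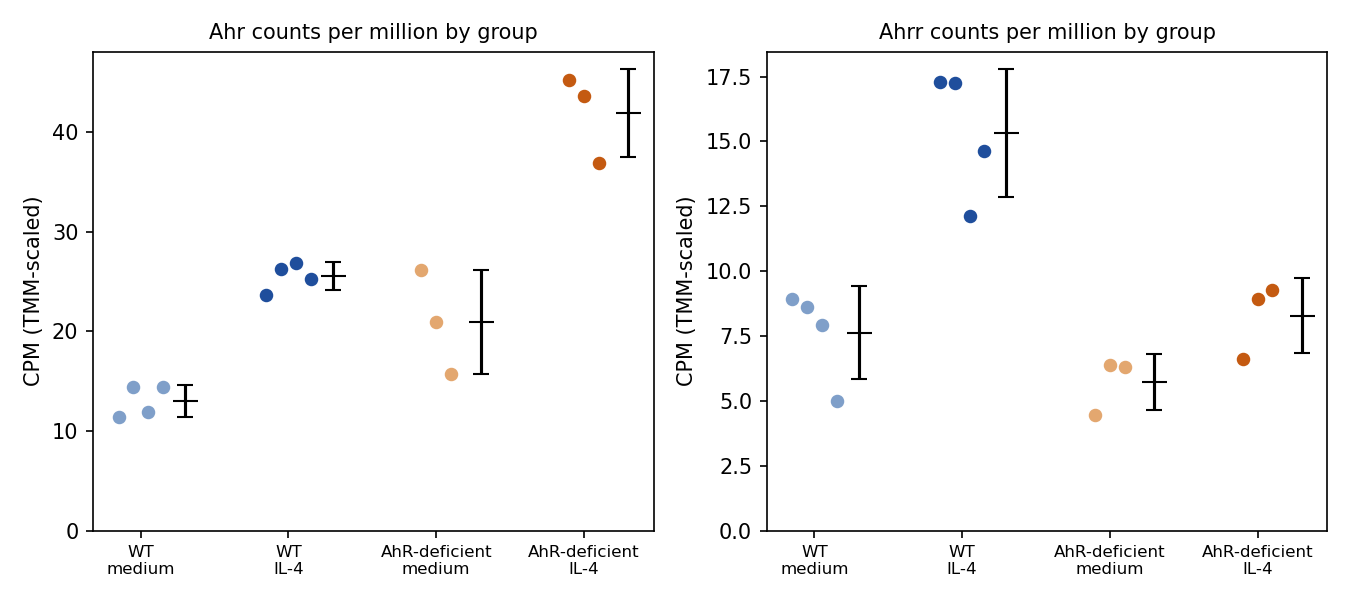
CPM of Ahr (left) and Ahrr (right) in each of the 14 libraries, by group. Points are libraries and the black marks give the mean ± SD of each group (n = 4 wild type, n = 3 AhR-deficient). Ahr lies at 11.4 to 14.4 CPM in wild type and 15.7 to 26.1 CPM in AhR-deficient cells in medium, and at 23.7 to 26.9 and 36.9 to 45.2 CPM in IL-4.

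The genotypes also differed in sex-linked transcripts. Xist is the RNA that silences an X chromosome in female cells. It stood at 987 CPM or more in all 6 AhR-deficient libraries and at 2.12 CPM or less in all 8 wild-type libraries. The Y-linked genes Ddx3y, Kdm5d and Uty had 0 counts in AhR-deficient cells in medium, against 132 ± 12.9, 47.2 ± 4.90 and 29.1 ± 2.90 CPM in wild type. Set against 3 counts over the group, these are at least 4886-fold, 1747-fold and 1075-fold lower. Eif2s3y had 1 count in AhR-deficient cells in medium and 14287 in wild type, a ratio of 10750.0 (exact 95% interval 1929 to 424600.0, counting error only). Every library thus carried the sex-linked transcripts of its own genotype group, and the genotype comparisons are also comparisons of female-typed with male-typed libraries.

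IL-4 changed a large part of the wild-type transcriptome within 3 h, with Arg1 among the largest rises and Il1b among the largest falls. Arg1, the arginase that marks alternatively activated macrophages (ENSMUSG00000019987.9, GRCm38 chromosome 10, 24915221 to 24927484), rose from 0.0986 ± 0.0584 to 142 ± 34.4 CPM (log2 fold change 10.40 ± 0.32, n = 4 per group, adjusted p = 1.93e-11). Il1b, a central inflammatory cytokine (ENSMUSG00000027398.13, GRCm38 chromosome 2, 129364570 to 129371139), fell from 383 ± 182 to 24.2 ± 3.27 CPM (-3.98 ± 0.30, adjusted p = 1.34e-07). Among the other largest rises were the feedback inhibitors of cytokine signalling Socs1 (7.57 ± 0.20) and Cish (6.17 ± 0.20), the arginine transporter gene Slc7a2 (7.47 ± 0.20), and the chitinase-like gene Chil4 (7.44 ± 0.28). The mannose receptor gene Mrc1 (6.46 ± 0.19) and the transcriptional regulators Batf3 (6.97 ± 0.26) and Ppargc1b (6.26 ± 0.19) followed. B3gnt7 (7.16 ± 0.21), Prnp (6.16 ± 0.15) and Mir99ahg (5.88 ± 0.26) rose as well. Car4, a membrane-bound carbonic anhydrase gene, had 0 counts in medium and 9.59 ± 1.73 CPM in IL-4, at least 471-fold higher when set against 3 counts over the group. The largest falls included Acod1 (-4.35 ± 0.55), which encodes the itaconate-producing enzyme of inflammatory macrophages. Also among them were the lectin receptor gene Clec4d (-3.84 ± 0.27) and the innate sensors Naip1 (-3.82 ± 0.36) and Nod2 (-3.60 ± 0.36). So were the chemotactic receptors Ccr7 (-3.59 ± 0.62) and Fpr1 (-3.43 ± 0.30), the chemokine gene Cxcl10 (-3.57 ± 0.54) and the fatty acid receptor gene Gpr84 (-3.56 ± 0.48). Trim13 (-3.60 ± 0.45), Thbs1 (-3.54 ± 0.26) and the Notch ligand gene Jag1 (-3.42 ± 0.29) fell too. edgeR called 5296 genes, 2865 up and 2431 down, of which 726 and 571 changed by a log2 of 1 or more. All genes named in these sentences were apart in every library of the groups, as the naming rule required. So were 4461 of the 5296 called genes. Chance gives 2.86% for genes not picked by a test. The called genes were picked on these same libraries, so their share is no separate support.

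Of 31 gene lists fixed in advance, 5 were called for IL-4 in wild type. In the IL-4 and alternative activation list, 20 of 28 measured members rose, 3 fell and 5 did not pass (21 and 3 when adjusted over the list alone). The list had a median log2 fold change of 3.34 (camera adjusted p = 5.67e-47, adjusted p = 1.94e-04 with an estimated correlation). The interferon-regulatory factor gene Irf4 was among the risers (5.15 ± 0.12). A member with 0 counts in medium, set to its bound, left the median at 3.34. Among IL-4 receptor signalling components, 8 of 20 measured members rose, 3 fell and 9 did not pass (8 and 4 when adjusted over the list alone). Socs1, Cish and the adaptor gene Irs2 (1.56 ± 0.08) led the rises, while the receptor chain gene Il13ra1 fell (-1.95 ± 0.08). The list's mean was 0.82 and its median 0.07 (camera adjusted p = 0.00141, adjusted p = 0.661 with an estimated correlation). For inflammatory cytokine and NF-kB genes, 2 of 20 measured members rose, 13 fell and 5 did not pass (2 and 13 when adjusted over the list alone). Il18 (-1.64 ± 0.15), the prostaglandin synthase gene Ptgs2 (-2.45 ± 0.23) and the inflammasome gene Nlrp3 (-1.46 ± 0.14) fell. The median was -1.55 (camera adjusted p = 9.75e-04, adjusted p = 0.887 with an estimated correlation). In the NRF2 antioxidant list, which holds genes of glutathione, thioredoxin and iron handling, 2 of 18 measured members rose, 12 fell and 4 did not pass (2 and 13 when adjusted over the list alone). The ferritin gene Fth1 (-2.09 ± 0.14), Osgin1 (-1.26 ± 0.12) and Pgd (-0.43 ± 0.05) fell, and Gclm, a subunit of the glutathione-synthesis enzyme, rose (0.77 ± 0.08). The median was -0.33 (camera adjusted p = 0.00710, adjusted p = 0.844 with an estimated correlation). Ribosome biogenesis genes rose together: 22 of 24 measured members rose, 1 fell and 1 did not pass (22 and 1 when adjusted over the list alone). Tsr1 (1.06 ± 0.10), Rrp12 (0.83 ± 0.07), Wdr43 (0.55 ± 0.05) and Pes1 (0.52 ± 0.04) are examples. The median was 0.56 (camera adjusted p = 1.37e-11, adjusted p = 0.184 with an estimated correlation). Known AhR target genes went both ways, and the list was not called: 4 of 11 measured members rose, 5 fell and 2 did not pass (4 and 5 when adjusted over the list alone). Its median was -0.28 and its mean 0.08 (camera adjusted p = 0.755). Lpxn (1.5 ± 0.08) and Xdh (0.88 ± 0.06) rose, and Nfe2l2, which encodes NRF2, fell (-1.37 ± 0.19). The other 25 lists had adjusted p-values of 0.125 to 0.987. With the numbers as a block, 8 lists were called, adding unfolded protein and amino acid stress genes (up, adjusted p = 0.0291), non-classical monocyte genes (down, adjusted p = 0.0279) and dendritic cell genes (up, adjusted p = 0.0450, although the median without the block was -0.27). None of these 3 passed with an estimated correlation and the block (adjusted p = 0.703, 0.762 and 0.703).

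In AhR-deficient cells, IL-4 raised and lowered many of the same genes. Arg1 rose from 0.275 ± 0.144 to 186 ± 40.1 CPM (log2 fold change 9.36 ± 0.33, n = 3 per group, adjusted p = 1.20e-10). Il1b fell from 382 ± 18.7 to 31.1 ± 5.02 CPM (-3.62 ± 0.34, adjusted p = 1.93e-06). Chil4 (7.53 ± 0.34), Socs1 (7.02 ± 0.22), B3gnt7 (6.97 ± 0.26), Slc7a2 (6.84 ± 0.21) and Batf3 (6.54 ± 0.28) were again among the largest rises. Mrc1 (6.30 ± 0.22), Ppargc1b (5.83 ± 0.22) and Prnp (5.64 ± 0.16) were too, joined by Tbc1d16 (6.05 ± 0.17) and the endothelin gene Edn1 (5.71 ± 0.31). Car4 had 1 count in medium and 1147 in IL-4, a ratio of 1114 (exact 95% interval 199.5 to 44030.0, counting error only). Acod1 (-4.24 ± 0.61), Naip1 (-3.89 ± 0.41), the type III interferon receptor gene Ifnlr1 (-3.76 ± 0.43), Cxcl10 (-3.49 ± 0.57), Clec4d (-3.39 ± 0.30) and Nod2 (-3.26 ± 0.40) were among the largest falls beside Il1b. Trim13 (-3.24 ± 0.49), Fpr1 (-3.22 ± 0.34), Adgb (-3.21 ± 0.48), Jag1 (-3.15 ± 0.31) and Zmynd15 (-3.13 ± 0.45) fell too. edgeR called 4359 genes, 2265 up and 2094 down, of which 662 and 565 changed by a log2 of 1 or more. Of the 4359, 4277 were apart in every library of the groups, where chance gives 10% for genes not picked by a test.

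The lists called in AhR-deficient cells were the 5 called in wild type. In the IL-4 and alternative activation list, 21 of 28 measured members rose, 2 fell and 5 did not pass (21 and 3 when adjusted over the list alone), and Irf4 rose by 5.05 ± 0.14. Its median was 3.36 (camera adjusted p = 1.47e-47, adjusted p = 3.14e-04 with an estimated correlation). Of the IL-4 receptor signalling components, 7 of 20 measured members rose, 4 fell and 9 did not pass (8 and 4 when adjusted over the list alone). Cish (5.54 ± 0.22) and Irs2 (1.40 ± 0.10) rose and Il13ra1 (-1.83 ± 0.10) fell. The list's mean was 0.71 and its median 0.12 (camera adjusted p = 0.00503, adjusted p = 0.677 with an estimated correlation). Inflammatory cytokine and NF-kB genes fell in part: 2 of 20 measured members rose, 11 fell and 7 did not pass (2 and 11 when adjusted over the list alone). Il18 (-1.91 ± 0.17), Nlrp3 (-1.48 ± 0.16) and the NF-kB regulator gene Nfkbiz (-2.67 ± 0.34) were among those that fell. The list's median was -1.27 (camera adjusted p = 0.00236, adjusted p = 0.866 with an estimated correlation). In the NRF2 antioxidant list, 1 of 18 measured members rose, 13 fell and 4 did not pass (1 and 13 when adjusted over the list alone). Its median was -0.43 (camera adjusted p = 2.47e-06, adjusted p = 0.406 with an estimated correlation). Fth1 (-2.30 ± 0.17), Osgin1 (-1.69 ± 0.13) and Pgd (-0.61 ± 0.06) fell, and the malic enzyme gene Me1 rose (2.97 ± 0.36). Of the ribosome biogenesis genes, 22 of 24 measured members rose, 0 fell and 2 did not pass (22 and 0 when adjusted over the list alone). Tsr1 (1.23 ± 0.12), Dkc1 (1.05 ± 0.09), Wdr43 (0.71 ± 0.05) and Pes1 (0.52 ± 0.05) rose. The list's median was 0.69 (camera adjusted p = 9.32e-16, adjusted p = 0.0751 with an estimated correlation). With the numbers as a block, ribosome biogenesis also passed with an estimated correlation (adjusted p = 0.0470), and dendritic cell genes joined the called lists (up, camera adjusted p = 7.47e-03, although the median without the block was -0.10). With an estimated correlation and the block, the dendritic cell list did not pass (adjusted p = 0.621). The AhR target list was not called: 3 of 11 measured members rose, 3 fell and 5 did not pass (4 and 3 when adjusted over the list alone). Its median was -0.15 and its mean 0.10 (camera adjusted p = 0.660). Lpxn (1.84 ± 0.10) and Xdh (0.94 ± 0.07) rose, and Nfe2l2 (-1.30 ± 0.21) and Nqo1 (-1.35 ± 0.24) fell. The other 25 lists had adjusted p-values of 0.102 to 0.995.

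The IL-4 responses of the genotypes overlapped widely, and whether any single gene responded differently depended on the tool, with 0 genes called by edgeR and 3 by DESeq2. Of the called genes, 1985 rose in both genotypes (439.8 expected if the calls were unrelated), 1739 fell in both (345 expected) and 0 went opposite ways. With the numbers as a block, 4 went opposite ways, chosen for naming after their values were seen. Sesn2 rose in wild type (0.16 ± 0.05) and fell in AhR-deficient cells (-0.24 ± 0.06). Fos (-0.43 ± 0.07 and 0.24 ± 0.08), Fosl2 (-0.28 ± 0.07 and 0.31 ± 0.08) and Sik1 (-0.25 ± 0.06 and 0.35 ± 0.07) fell in wild type and rose in AhR-deficient cells. The interaction of these 4 did not pass with the block (adjusted p = 0.102 to 0.208). Log2 fold changes of the genotypes, which share no library, correlated across the 14754 genes at a Pearson r of 0.866 and a Spearman rho of 0.77, where genes are not independent replicates. Of the genes called in wild type, 98.62% had the same sign in AhR-deficient cells. edgeR called 0 genes for the interaction, the difference between the IL-4 responses. At an unadjusted p under 0.05 there were 558 genes, where 737.7 are expected with no difference. This fit leaves out the pairing of the libraries by number, so the low count is not evidence of equal responses. With the numbers as a block, edgeR again called 0 genes (smallest adjusted p = 0.102), with 1252 at an unadjusted p under 0.05. Limma-voom with the block also called 0, with 1269 at that p, and DESeq2 with the block called 60. Without the block, limma-voom called 0 genes (544 at an unadjusted p under 0.05) and DESeq2 called 3. The genes called by DESeq2 were Rmi2, Rnf24 and Gclm, with DESeq2 log2 values of -0.74, -0.88 and -0.62 (adjusted p = 3.44e-04, 3.44e-04 and 0.0285). In edgeR these failed, with Rmi2 at -0.76 ± 0.12 and Rnf24 at -0.89 ± 0.14 (adjusted p = 0.179 for both). So did Gclm at -0.63 ± 0.13 (adjusted p = 0.955). Hes1 (0.90 ± 0.19) and Glcci1 (-1.17 ± 0.25) had the next smallest p-values and failed too. Of the exon bases of Glcci1, 69.8% lie under exons of another gene on the same strand. For Ahr, the difference was 0.03 ± 0.20. The median standard error of an interaction was 0.155. Simulated data had as many libraries but no pairing by number, and were tested without the block. There, 23.9% of 1.5-fold and 58.2% of 2-fold interactions were recovered, so differences of this size can be missed.

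By camera, 6 lists differed between genotypes in their IL-4 response, none of them with an estimated correlation or by fry. An interaction is also the genotype difference in IL-4 minus that in medium. These calls are thus not separate from the genotype differences of lists given below. NRF2 antioxidant genes, of which 12 fell with IL-4 in wild type and 13 in AhR-deficient cells, had a median difference between the responses (AhR-deficient minus wild type) of -0.21 (adjusted p = 7.56e-07, adjusted p = 0.728 with an estimated correlation). For unfolded protein and amino acid stress genes the median was -0.12 (adjusted p = 5.08e-05, adjusted p = 0.728 with an estimated correlation), and for cholesterol synthesis genes -0.20 (adjusted p = 7.83e-04, adjusted p = 0.728 with an estimated correlation). Cell cycle genes stood at -0.08 (adjusted p = 0.00778) and oxidative phosphorylation genes at -0.05 (adjusted p = 0.0150), with an adjusted p of 0.978 at an estimated correlation for each. Ribosome biogenesis genes, which rose in both genotypes, had a median of 0.06 (adjusted p = 0.00510, adjusted p = 0.766 with an estimated correlation). No member passed over all genes tested. Adjusted over the list alone, 1 member passed in the NRF2 list, Gclm, and 1 in the stress list, Sesn2 (-0.39 ± 0.10), and 0 passed in the other 4. The block added granulocyte and monocyte progenitor markers (down, adjusted p = 0.0209), which did not pass with an estimated correlation and the block (adjusted p = 0.807). The call ended without numbers 1 and 2 for cholesterol synthesis (adjusted p = 0.310) and ribosome biogenesis genes (0.0621), and with the granulocyte covariate for cell cycle genes (0.0530).

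**Figure D2:**
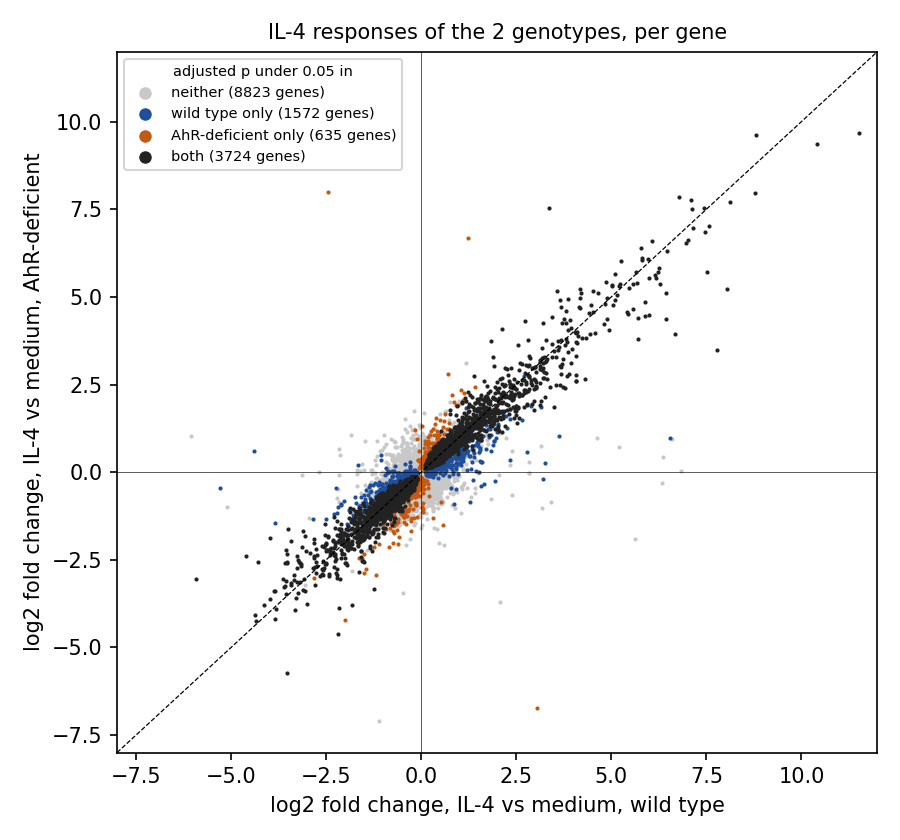
Log2 fold change of each of the 14754 genes with IL-4 in wild type (horizontal axis) and in AhR-deficient cells (vertical axis). Colours give the genes called in both (3724), in wild type and not in AhR-deficient cells (1572), in AhR-deficient and not in wild type (635) or in neither (8823). The dashed line marks equal change. edgeR called 0 genes for the difference between the axes (558 at an unadjusted p under 0.05), and DESeq2 called 3. Fitted values of genes with almost no counts in a group depend on the prior count.

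In medium, AhR-deficient cells had higher levels of genes of amino acid stress and of antioxidant defence, and lower Ccr2. Gdf3, a TGF-beta family ligand gene (ENSMUSG00000030117.5, GRCm38 chromosome 6, 122605403 to 122610087), stood at 17.1 ± 3.30 against 2.53 ± 0.744 CPM in wild type (log2 difference 2.76 ± 0.21, n = 3 and 4, adjusted p = 1.01e-05). Ccr2, the receptor that guides monocytes out of the bone marrow (ENSMUSG00000049103.14, GRCm38 chromosome 9, 124101950 to 124113557), stood at 381 ± 85.0 against 1277 ± 549 CPM (-1.75 ± 0.31, adjusted p = 0.00985). In the unfolded protein and amino acid stress list, 11 of 21 measured members were higher, 0 were lower and 10 did not pass (16 and 0 when adjusted over the list alone). The stress regulators Trib3 (1.12 ± 0.12), Ddit3 (0.69 ± 0.08) and Sesn2 (0.63 ± 0.07) and the amino acid transporter gene Slc3a2 (0.55 ± 0.06) were higher. The median was 0.50 (camera adjusted p = 2.49e-18, adjusted p = 0.124 with an estimated correlation). In the NRF2 antioxidant list, 13 of 18 measured members were higher, 0 were lower and 5 did not pass (14 and 0 when adjusted over the list alone). Examples are the cystine transporter gene Slc7a11 (1.75 ± 0.28), Gclm (0.68 ± 0.09), Srxn1 (1.10 ± 0.18) and the ferritin gene Ftl1 (0.44 ± 0.08). The median was 0.38 (camera adjusted p = 3.80e-11, adjusted p = 0.202 with an estimated correlation). Beside these, markers of eosinophils, another cell type of the bone marrow, had a median difference of -1.31 (0 of 9 called, camera adjusted p = 0.0132, adjusted p = 0.607 with an estimated correlation). Among the other largest differences, Bmpr1a (2.20 ± 0.45), Lrrc32 (2.14 ± 0.42), the platelet and endothelial adhesion gene Selp (1.94 ± 0.44), and Ednrb (1.75 ± 0.43) were higher. Rnf128 (1.62 ± 0.24), the cyclin gene Ccnd2 (1.59 ± 0.23) and Upp1 (1.51 ± 0.39) were also higher, as were Ifi205 (1.72 ± 0.44) and H2-Q6 (1.63 ± 0.37). The last pair have close relatives in their families that can share reads. Fbxo32 (-1.35 ± 0.25), Ypel2 (-1.33 ± 0.28), Lpar5 (-1.25 ± 0.30) and the prostaglandin-degrading enzyme gene Hpgd (-1.20 ± 0.24) were lower, and so were Stag3 (-1.19 ± 0.24), Fam187b (-1.10 ± 0.25) and Frat2 (-1.10 ± 0.22). edgeR called 1197 genes, 614 higher and 583 lower in AhR-deficient cells. Of these, 1146 lay on autosomes, 41 on the X chromosome, 6 on the Y chromosome and 4 on mitochondrial DNA. The last 4 were all lower in AhR-deficient cells. Of the 1197, 1133 were apart in every library (chance gives 5.71% for genes not picked by a test). The count was 661 without wild-type number 1, 367 without number 2, 95 without AhR-deficient number 4 and 688 without number 6. It was 59 with only the groups compared in the model, 1990 with DESeq2, 388 with a granulocyte marker score as covariate and 30 without numbers 1 and 2, the wild-type pairs richest in eosinophil transcripts. Gdf3, Trib3, Ddit3, Sesn2, Slc3a2, Slc7a11, Gclm, Srxn1, Rnf128, Ccnd2, Srebf2 and Gpnmb passed in each of the 7 fits without 1 library. All other autosomal genes named as higher or lower in medium kept their direction. They missed the threshold without AhR-deficient number 4 (Ccr2 at adjusted p = 0.0720), except Fcgr1, which missed it without number 6 (adjusted p = 0.0566).

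Camera called 11 further lists between genotypes in medium, and none of the 14 passed with an estimated correlation (adjusted p-values of 0.124 to 0.683). Interferon-stimulated genes were higher in part: 4 of 30 measured members were higher, 0 were lower and 26 did not pass (23 and 0 when adjusted over the list alone). Their median was 0.76 (camera adjusted p = 9.91e-09, adjusted p = 0.605 with an estimated correlation). Isg20 (0.63 ± 0.13), Oasl1 (1.18 ± 0.26), Rsad2 (0.97 ± 0.26) and Isg15 (1.12 ± 0.31, groups overlapping) passed. The mean log2 CPM of the list was 4.375 and 4.605 in AhR-deficient numbers 4 and 6 but 3.493 in number 5, against 3.372 to 3.52 in wild type. For cholesterol synthesis genes, 6 of 23 measured members were higher, 0 were lower and 17 did not pass (10 and 0 when adjusted over the list alone). The sterol regulator gene Srebf2 (0.37 ± 0.05) and Sqle (0.72 ± 0.16) were higher. The list's median was 0.35 (camera adjusted p = 4.51e-04, adjusted p = 0.536 with an estimated correlation). Among antigen presentation and costimulation genes, 3 of 20 measured members were higher, 0 were lower and 17 did not pass (8 and 0 when adjusted over the list alone). Their median was 0.33 (camera adjusted p = 4.24e-05, adjusted p = 0.511 with an estimated correlation). The class I gene H2-K1 (0.56 ± 0.12) is an example whose relatives can share reads. Of the macrophage genes, 5 of 21 measured members were higher, 1 was lower and 15 did not pass (6 and 1 when adjusted over the list alone). Their median was 0.26 (camera adjusted p = 0.00929, adjusted p = 0.536 with an estimated correlation). Gpnmb (0.93 ± 0.13), the haem oxygenase gene Hmox1 (0.83 ± 0.17), the Fc receptor gene Fcgr1 (0.60 ± 0.12) and the cathepsin gene Ctsb (0.51 ± 0.12) were higher. In the immediate early list, 4 of 20 measured members were higher, 0 were lower and 16 did not pass (7 and 1 when adjusted over the list alone). Its median was 0.32 (camera adjusted p = 0.00838, adjusted p = 0.607 with an estimated correlation). Jun (0.70 ± 0.12), Myc (0.71 ± 0.13) and Fosl1 (1.25 ± 0.22) were higher, although 57.2% of the exon bases of Fosl1 lie under a gene on the opposite strand. For the IL-4 and alternative activation list, 1 of 28 measured members was higher, 0 were lower and 27 did not pass (1 and 0 when adjusted over the list alone), with Klf4 at 0.37 ± 0.07. Its median was 0.34 (camera adjusted p = 0.00226, adjusted p = 0.511 with an estimated correlation). Of the inflammatory genes, 1 of 20 measured members was higher, 0 were lower and 19 did not pass (3 and 0 when adjusted over the list alone). Their median was 0.49 (camera adjusted p = 0.00554, adjusted p = 0.617 with an estimated correlation). For ribosome biogenesis genes, 3 of 24 measured members were higher, 0 were lower and 21 did not pass (4 and 0 when adjusted over the list alone). Their median was 0.13 (camera adjusted p = 0.0172, adjusted p = 0.607 with an estimated correlation). Among dendritic cell genes, 1 of 17 measured members was higher, 0 were lower and 16 did not pass (3 and 0 when adjusted over the list alone), the lectin receptor gene Clec9a standing at 0.57 ± 0.10. The list's median was 0.40 (camera adjusted p = 0.00554, adjusted p = 0.511 with an estimated correlation). For granulocyte and monocyte progenitor markers, 1 of 12 measured members was higher, 0 were lower and 11 did not pass (3 and 0 when adjusted over the list alone). Their median was 0.44 (camera adjusted p = 0.0462, adjusted p = 0.663 with an estimated correlation). For erythroid markers, 0 of 13 measured members were higher, 0 were lower and 13 did not pass (0 and 0 when adjusted over the list alone). Their median was -0.48 (camera adjusted p = 0.0289, adjusted p = 0.683 with an estimated correlation). The AhR target list was not called (1 of 11 measured members was higher, 2 were lower and 8 did not pass, 1 and 2 when adjusted over the list alone, camera adjusted p = 0.677). Nqo1 was higher (0.89 ± 0.22), while Tiparp (-0.33 ± 0.08) and Ugt1a7c (-0.21 ± 0.05, 54.6% of exon bases shared with related genes on its strand) were lower. The other 16 lists had adjusted p-values of 0.0545 to 0.916. Without numbers 1 and 2, the camera call ended for 7 of the 14 lists in medium: IL-4 and alternative activation (adjusted p = 0.0540), inflammatory (0.115), ribosome biogenesis and immediate early (0.0992 each), dendritic cell (0.0826), erythroid (0.0916) and eosinophil (0.379). With the granulocyte covariate it ended for macrophage genes (adjusted p = 0.0932), erythroid markers (0.282) and eosinophil markers (0.596). For granulocyte and monocyte progenitor markers the camera adjusted p fell instead. It was 4.04e-06 without numbers 1 and 2 and 6.84e-05 with the covariate.

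**Figure D3:**
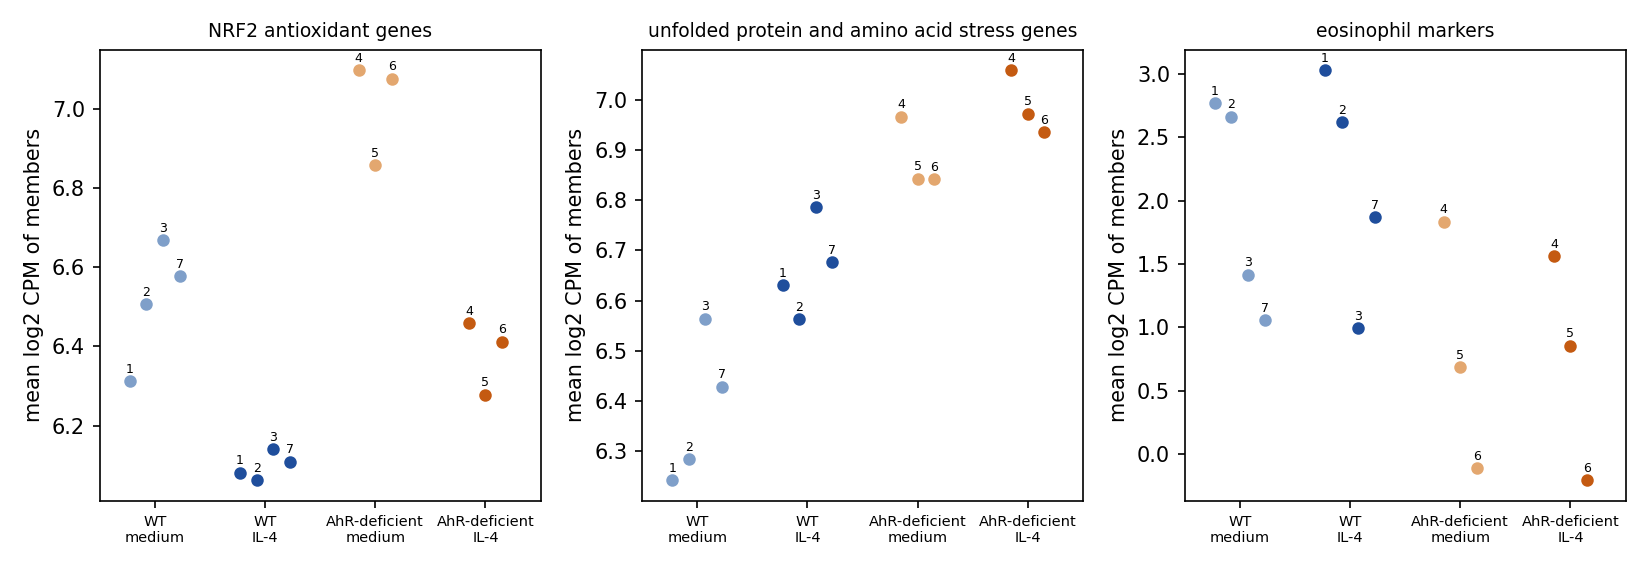
Mean log2 CPM of the members of the NRF2 antioxidant, unfolded protein and amino acid stress, and eosinophil marker lists in each of the 14 libraries, by group. Each point is a library with its number. In medium every AhR-deficient library lies above every wild-type library for both stress lists, and eosinophil markers spread widely within each group.

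In IL-4, Gdf3 was again higher and Ccr2 again lower in AhR-deficient cells. Gdf3 stood at 15.8 ± 2.83 against 2.90 ± 0.528 CPM (2.45 ± 0.21, n = 3 and 4, adjusted p = 2.78e-05). Ccr2 stood at 508 ± 49.2 against 1714 ± 106 CPM (-1.75 ± 0.31, adjusted p = 0.0204). The Fc receptor gene Fcgr1 (0.97 ± 0.13), Gpnmb (1.05 ± 0.14), the dendritic cell lectin receptor gene Clec9a (0.81 ± 0.10) and the stress regulator Ddit3 (0.60 ± 0.08) were higher, and the protease inhibitor gene Spint1 was lower (-1.02 ± 0.13). Selp (2.21 ± 0.46), Flrt3 (2.18 ± 0.40), Bmpr1a (2.14 ± 0.44), the MAP kinase phosphatase gene Dusp4 (1.78 ± 0.32) and the IL-7 receptor gene Il7r (1.56 ± 0.26) were also higher. So were Lrrc32 (1.48 ± 0.34), Slc7a11 (1.43 ± 0.29), Fosl1 (1.26 ± 0.25) and H2-Q6 (1.67 ± 0.38). Card10 (-1.12 ± 0.23), Stag3 (-1.06 ± 0.24), F11r (-1.03 ± 0.17), the metalloprotease inhibitor gene Timp2 (-0.97 ± 0.18), Cd109 (-0.95 ± 0.16) and the desaturase gene Scd2 (-0.94 ± 0.17) were lower. Eosinophil markers had a median difference of -1.53 (0 of 9 called and 1 lower when adjusted over the list alone, camera adjusted p = 3.54e-04, adjusted p = 0.425 with an estimated correlation). Neutrophil markers had a median of -0.86 (0 of 15 called, 1 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.00578, adjusted p = 0.485 with an estimated correlation). edgeR called 239 genes, 141 higher and 98 lower. On autosomes lay 218, on the X 15 and on the Y chromosome 6. The libraries of the groups were apart for all 239 (chance gives 5.71% for genes not picked by a test). The count was 34, 35 and 106 without wild-type number 1, 2 or 7, and 24 and 30 without AhR-deficient number 4 or 5. It was 23 with the granulocyte covariate, 25 without numbers 1 and 2, 361 with no filter, 420 with the numbers as a random block and 802 with DESeq2. With only the groups compared in the model it was 523, more than the 59 in medium, so which condition held more calls depended on the model. Gdf3, Fcgr1, Gpnmb, Clec9a, Ddit3 and Spint1 passed in each of the 7 fits without 1 library. Each other autosomal gene named as higher or lower in IL-4 kept its direction but missed the threshold without AhR-deficient number 4 and without number 5 (adjusted p of Ccr2 up to 0.113).

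Camera called 12 further lists in IL-4, and none of the 14 passed with an estimated correlation (adjusted p-values of 0.298 to 0.485). For unfolded protein and amino acid stress genes, 4 of 21 measured members were higher, 0 were lower and 17 did not pass (11 and 0 when adjusted over the list alone). Their median was 0.28 (camera adjusted p = 1.67e-10, adjusted p = 0.298 with an estimated correlation). Trib3 (0.72 ± 0.12), Slc3a2 (0.39 ± 0.06) and Atf4 (0.25 ± 0.05) were higher beside Ddit3. Of the interferon-stimulated genes, 3 of 30 measured members were higher, 0 were lower and 27 did not pass (8 and 0 when adjusted over the list alone). Their median was 0.66 (camera adjusted p = 2.10e-10, adjusted p = 0.425 with an estimated correlation). Oasl1 (1.24 ± 0.27), Rsad2 (1.16 ± 0.27) and Isg15 (1.33 ± 0.31) passed. Number 5 again stood at a mean log2 CPM within the wild-type range (3.501 against 2.783 to 3.624), with numbers 4 and 6 at 4.096 and 4.38. For the dendritic cell list, 2 of 17 measured members were higher, 0 were lower and 15 did not pass (7 and 0 when adjusted over the list alone), with Irf8 at 0.40 ± 0.09. Its median was 0.49 (camera adjusted p = 2.26e-06, adjusted p = 0.298 with an estimated correlation). For the macrophage list, 2 of 21 measured members were higher, 0 were lower and 19 did not pass (7 and 1 when adjusted over the list alone). Its median was 0.14 (camera adjusted p = 3.13e-04, adjusted p = 0.299 with an estimated correlation). In the cell cycle list, 0 of 22 measured members were higher, 2 were lower and 20 did not pass (0 and 14 when adjusted over the list alone), with the mitotic genes Cenpf (-0.36 ± 0.07) and Cenpe (-0.37 ± 0.08) lower. The list's median was -0.19 (camera adjusted p = 5.96e-06, adjusted p = 0.425 with an estimated correlation). Of the NRF2 genes, 1 of 18 measured members was higher, 0 were lower and 17 did not pass (7 and 1 when adjusted over the list alone). Their median was 0.20 (camera adjusted p = 7.53e-04, adjusted p = 0.425 with an estimated correlation). Of the immediate early genes, 2 of 20 measured members were higher, 0 were lower and 18 did not pass (4 and 0 when adjusted over the list alone), with Myc at 0.57 ± 0.12. Their median was 0.27 (camera adjusted p = 7.04e-04, adjusted p = 0.445 with an estimated correlation). Of the IL-4 and alternative activation genes, 1 of 28 measured members was higher, 0 were lower and 27 did not pass (6 and 0 when adjusted over the list alone), the lectin receptor gene Clec10a standing at 0.44 ± 0.10. The list's median was 0.29 (camera adjusted p = 6.22e-04, adjusted p = 0.327 with an estimated correlation). No member passed over all genes in 4 further lists. In the ribosome biogenesis list 12 of 24 measured members were higher and 0 lower when adjusted over the list alone. Its median was 0.18 (camera adjusted p = 3.93e-08, adjusted p = 0.298 with an estimated correlation). Of the antigen presentation genes, 10 of 20 measured members were higher and 0 lower when adjusted over the list alone. Their median was 0.38 (camera adjusted p = 1.68e-06, adjusted p = 0.299 with an estimated correlation). For the inflammatory list the numbers were 1 higher and 0 lower of 20 measured members when adjusted over the list alone. Its median was 0.63 (camera adjusted p = 1.97e-05, adjusted p = 0.425 with an estimated correlation). For platelet and megakaryocyte markers they were 4 higher and 0 lower of 6 measured members when adjusted over the list alone. Their median was 0.97 (camera adjusted p = 0.0137, adjusted p = 0.425 with an estimated correlation). The AhR target list was not called (0 of 11 measured members were higher, 1 was lower and 10 did not pass, 1 and 1 when adjusted over the list alone, camera adjusted p = 0.686), Ahrr being the member that passed. The other 16 lists had adjusted p-values of 0.0731 to 0.866. The camera call in IL-4 ended for platelet and megakaryocyte markers without numbers 1 and 2 (adjusted p = 0.0970), and for neutrophil (0.877) and eosinophil markers (0.631) with the granulocyte covariate. With that covariate, platelet and megakaryocyte markers had a smaller camera adjusted p of 0.0014.

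**Figure D4:**
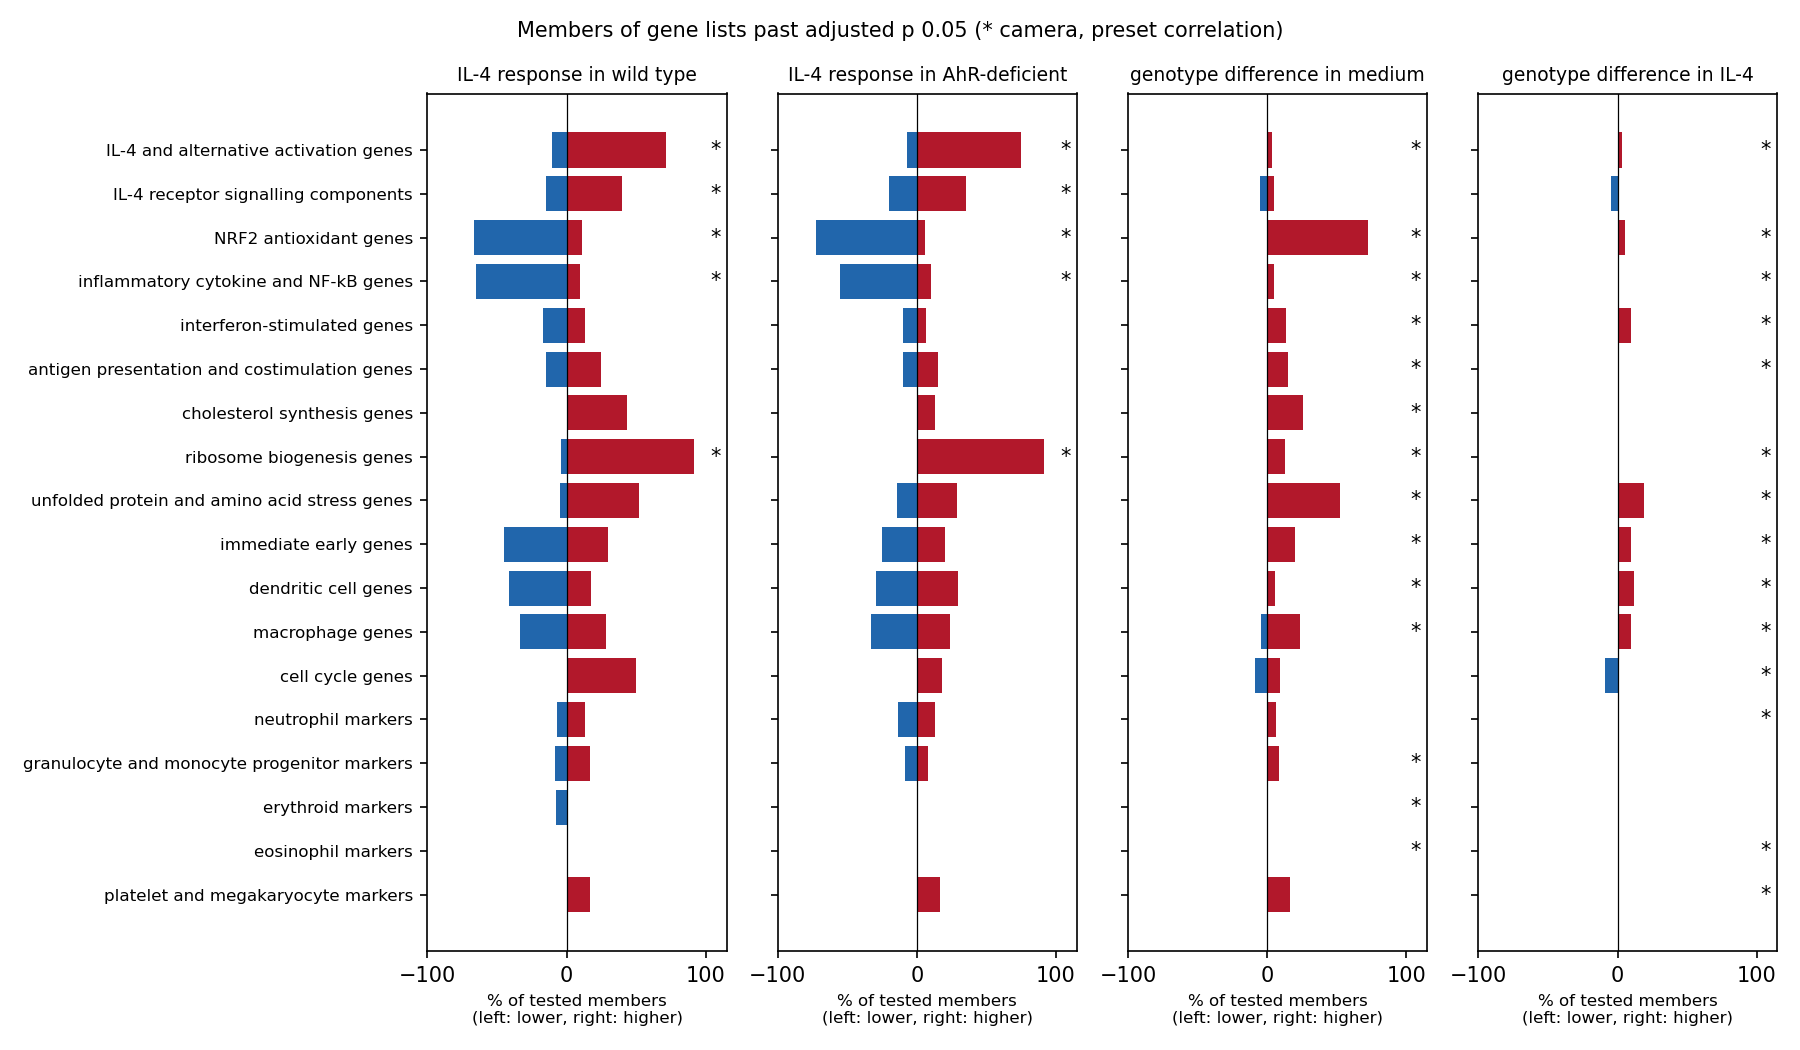
Share of the measured members of each gene list called in at least 1 comparison that were higher (red, right) or lower (blue, left) with adjusted p under 0.05, for the IL-4 responses and the genotype differences. An asterisk marks lists with a camera adjusted p under 0.05 at the preset correlation. The NRF2 list has 12 members lower with IL-4 in wild type and 13 higher in AhR-deficient cells in medium.

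Genotype differences in medium and in IL-4 involved some of the same genes: 92 were higher in both (5.9 expected if unrelated), 68 were lower in both (3.9 expected) and 0 were opposite. These expected counts leave out that the comparisons share their numbers. The differences correlated across genes at r = 0.664 and rho = 0.591, where the other 34 splits of the 7 numbers into 4 and 3 gave r of 0.222 to 0.621. The cells of a given number gave a library to each condition, so the conditions are not independent here. Genes within 20 Mb of Ahr, where DNA of another strain can accompany a targeted allele, were called at a share of 8.04% in medium (9 of 112). The share of the other autosomal genes was 8.01% (odds ratio 1.003, p = 1, adjusted p = 1 over 2 tests, Fisher's exact test, two-sided). In IL-4 the shares were 3.57% (4 of 112) and 1.5%, which did not pass (odds ratio 2.43, p = 0.0911, adjusted p = 0.182, same exact test). With flanks of 5 and 40 Mb the odds ratios were 1.08 and 1.07 in medium, and 3.96 (2 of 35 genes, Fisher's exact p = 0.0986) and 1.19 (4 of 223 genes, Fisher's exact p = 0.584) in IL-4, none of which passed.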

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

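Among the tests here, the other splits of the samples, the Ahr difference with a granulocyte covariate and the stress lists without each library were set before their results were seen. The granulocyte score was itself chosen after seeing the data, so the Ahr test with it was not fixed before the data were examined. The tests of sex-linked transcripts, of swapped libraries, of exchanged labels, of the interaction with a block, of an altered Ahr transcript, and of granulocyte transcripts in the called genes and the stress lists were chosen only after the result was seen.

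Other splits of the 7 numbers gave fewer genotype calls than the real one (1197 in medium, 239 in IL-4). Of the 35 splits into 4 and 3, 1 split, the real one, gave as many calls in each condition (highest other 964 in medium and 17 in IL-4). A share of 1 in 35 is the smallest that these splits can give, and the conditions share their numbers. The share lies under 0.05 and argues against chance, but cannot exclude it. The split with 964 set numbers 1, 2 and 7 against 3, 4, 5 and 6 and shared 471 genes with the real one (78.2 expected), all reversed in sign (r = -0.805 across genes), and so sets wild-type number 3 with the AhR-deficient libraries. Whether granulocyte transcripts, which may enter from other cells, are the whole source could not be decided. With their score as covariate, the called genes kept a slope of 0.986 on their unadjusted log2 differences in medium (0.956 for autosomal genes, 0.893 to 0.984 over fits without 1 library). In IL-4 the slope was 0.989 (0.918 for autosomal genes, 0.848 to 0.954 over such fits). These genes were picked in the unadjusted fit, which favours a small spread within groups. The score itself varied within groups (SD of 0.496 to 0.646), so a slope near 1 is partly set by that choice. Most calls ended with the covariate (1197 to 388 in medium, 364 shared, and 239 to 23 in IL-4, 21 shared). The median size fell from 0.396 to 0.384 in medium and from 0.499 to 0.469 in IL-4. The median standard error grew from 0.092 to 0.102 and from 0.095 to 0.116. Sex and AhR genotype cannot be told apart for these genes, since 14 of 14 libraries carry the sex-linked transcripts of their genotype group, and the share of mitochondrial counts was lower in every library labelled AhR-deficient (0.907 to 0.962% against 1.06 to 1.10% in medium, 0.898 to 0.943% against 0.944 to 1.08% in IL-4), so AhR, sex, cell or RNA quality (untested) and other differences between the groups all stay open.

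Ahr counts were higher in the libraries labelled AhR-deficient (log2 difference 0.69 in medium and 0.71 in IL-4). A swap of single libraries between the genotypes is argued against, since 0 libraries carried the sex-linked transcripts of the other genotype, and so are granulocyte transcripts, since with their score as covariate the difference was 0.772 ± 0.146 (SE, adjusted p = 0.0234) in medium and 0.851 ± 0.157 (adjusted p = 0.0627) in IL-4, the latter call ending as the SE grew from 0.137. An exchange of the labels of the whole genotype groups cannot be told apart from correct labels, since the labels give no sex and Ahrr, a known AhR target, was lower in the libraries labelled AhR-deficient (log2 difference -0.886 in IL-4 and -0.415 in medium) but passed in only 1 of 7 fits without 1 library in IL-4 and in 0 of 7 in medium. The other AhR targets called in medium went both ways, Tiparp (-0.33) and Ugt1a7c (-0.21) lower and Nqo1 (0.89) higher. None of these 3 passed without AhR-deficient number 4, so they do not settle the labels. Reads of an altered or shortened transcript may be counted to the gene and cannot be told apart from an intact transcript, as the deposited table has 0 columns of exon counts, while an inactive transcript made in excess from a targeted allele and an effect of sex on Ahr are untested biological hypotheses.

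Both stress lists were higher in AhR-deficient cells in medium (median log2 difference 0.38 for NRF2 antioxidant genes and 0.50 for unfolded protein and amino acid stress genes). Granulocyte transcripts as the whole source are argued against, since with the covariate the lists kept shares of 0.951 and 0.882 of these medians (0.679 to 1.033 over fits without 1 library, the lowest value without AhR-deficient number 4 in medium). A single library is argued against too: without any 1 library the lists kept at least 0.83 and 0.813 of their medians, both lowest without AhR-deficient number 4. Sex cannot be told apart from genotype here, as 14 of 14 libraries match their group, cell or RNA quality stays open untested, and no list passed with an estimated correlation. Transcripts of other admixed cells, such as progenitors or platelets, were not tested as a source of these differences.

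For the IL-4 responses, 1 of the 35 splits of the 8 wild-type libraries gave as many calls, the real one with 5296 (highest other 2). The numbers pair these libraries, and the 8 splits that part all pairs (the 7 others gave 0) are too few for a share under 0.05. In AhR-deficient cells the 10 splits are too few for a share under 0.05 (real 4359, highest other 0; the 3 others that part all pairs gave 0). For the interaction the real count of called genes was 0, which 35 of 35 splits reach by design (highest other 0), so that count says nothing about chance. With the numbers as a block, 3 of the 35 genotype splits gave as many genes at an unadjusted p under 0.05 as the real one, 1252 (highest other 1548), so chance cannot be excluded for that number.

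A library lay far from the other 3 of its wild-type group in 12 of 293 sets of values, where chance gives 1 in 20 (14.7 expected). In CPM, in medium these were Batf3 in number 3 (0.944, others 0.303 to 0.401), Chil4 in number 7 (0.0573, others 0.110 to 0.121), H2-Q6 in number 1 (27.1, others 47.3 to 49.7) and Jun in number 1 (72.5, others 99.3 to 102). Also in medium were Pgd in number 3 (551, others 490.03 to 497) and Rmi2 in number 7 (4.15, others 5.23 to 5.38). In IL-4 they were Car4 in number 7 (12.2, others 8.50 to 9.10), Ifnlr1 in number 2 (2.85, others 1.37 to 1.42), Socs1 in number 3 (166, others 117 to 119) and Xist in number 7 (2.12, others 0.0507 to 0.158). Per library, number 3 in medium had 20290.0 genes detected (others 20115 to 20125) and number 1 in medium had 4.10% of its counts in ribosomal protein genes (others 3.52 to 3.55%).

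Lists whose IL-4 response differed between genotypes by the interaction test were NRF2 antioxidant (median log2 difference of -0.209), unfolded protein and amino acid stress (-0.123), cholesterol synthesis (-0.199), cell cycle (-0.082), oxidative phosphorylation (-0.053) and ribosome biogenesis genes (0.063), in each case by camera at the preset correlation and in 0 cases with an estimated correlation. The NRF2 and stress lists were already higher in AhR-deficient cells in medium (medians of 0.382 and 0.497) and less so in IL-4. Their interactions rest on the same libraries and are no separate finding.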

How the results depend on the processing

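The comparisons without numbers 1 and 2, with the granulocyte covariate, on autosomes alone and with the block in limma-voom or DESeq2 were chosen after seeing the data. The counts for IL-4 stayed within 1.5 times under every alternative run (without 1 library, 4644 to 5374 in wild type and 3621 to 3906 in AhR-deficient cells), and scaling moved the median of all genes by 0.016 at most. Shared IL-4 calls numbered 1004 with a log2 of 1 or more in both, since fewer genes enter.

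The genotype difference in medium gave 1990 genes with DESeq2, 59 with only the groups compared and 388 with the granulocyte covariate. With the numbers as a random block in limma-voom (correlation of 0.332 within a number) it gave 1375. It gave 30 without numbers 1 and 2, and 95 to 1716 without 1 library. The share of higher genes in medium was 51.3%, and ran from 39.1% without AhR-deficient number 6 to 70% without numbers 1 and 2. The genotype difference in IL-4 gave 802 genes with DESeq2, 361 with no filter, 523 with only the groups compared, 420 with a random block, 23 with the covariate, 25 without numbers 1 and 2, and 24 to 315 without 1 library. The share of higher genes in IL-4 was 59.0%, and ran from 47.8% with the granulocyte covariate to 70.1% with no filter. The interaction gave 3 genes with DESeq2, 60 with the block and DESeq2, and 0 to 0 without 1 library. Fewer samples enter where libraries are left out; otherwise the cause was not tested. Ahr was higher in AhR-deficient cells under every alternative, with log2 differences of 0.49 to 0.85 in medium and 0.66 to 0.80 in IL-4 without 1 library. Leaving out numbers 1 and 2, they were 0.663 (adjusted p = 0.166) and 0.692 (adjusted p = 0.218).

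Lists called with an estimated correlation numbered 1 in each IL-4 response and 0 in the genotype differences and the interaction. By fry they numbered 16 and 10 in the IL-4 responses of wild type and AhR-deficient cells, 8 and 5 in the genotype differences in medium and in IL-4, and 0 in the interaction. Of the 14 camera calls in medium, fry kept 7 and lost 7. The stress (fry adjusted p = 8.17e-04) and NRF2 lists (0.00178) passed, and the interferon list (0.0913) failed. In IL-4 fry kept 5 and lost 9. There the stress list passed (fry adjusted p = 0.0114), and the NRF2 (0.0848) and interferon lists (0.113) failed. The block gave 8 in the IL-4 response in wild type, and leaving out numbers 1 and 2 gave 8 between genotypes in medium, where 7 of the 14 calls ended. Only the granulocyte covariate, which removes the trend it measures, turned lists between genotypes in IL-4: the neutrophil list (adjusted p = 0.877) and the eosinophil list (adjusted p = 0.631) turned positive.

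Over the genes reported from the naming rule and those added to it, direction and side of the threshold stayed the same in 727 of 737 values in the IL-4 response in wild type, 636 of 650 in AhR-deficient cells, 715 of 931 in the genotype difference in medium (176 no longer passed), 728 of 926 in IL-4 (96 no longer passed) and 453 of 463 in the interaction. With the numbers as a block, 7 of 171 gene calls changed, all of which passed with IL-4: Ahrr, Fos and Fosl2 in AhR-deficient cells, Sesn2 and Ptges3 (log2 fold change 0.13, adjusted p = 0.0375) in wild type, and Sik1 in both. Of genes called for IL-4 in both genotypes, 4 went opposite ways with the block and 0 without it. The granulocyte covariate turned genotype differences of uncalled eosinophil genes positive: Ear1 (0.002) and Prg2 (0.156) in medium, and Epx (0.017), Ear1 (0.126), Ear6 (0.05) and Prg2 (0.362) in IL-4. Without numbers 1 and 2, Prg2 stood at 0.071 in medium. Uncalled interactions near 0 changed sign without a library (Ahr to -0.021, Arnt to -0.003). Counting depth limits the genes near the floor of 3 counts. Between replicates the counts spread more than counting error allows (chi-square per degree of freedom of 13.8 to 60.0 over pairs of replicates). These values pool genes of high and low counts, so up to which count level depth is the limit was not tested.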

Other observations

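All genes in this part were chosen after their values were seen.

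Some lists that were not called for IL-4 held large changes in both directions. Kynurenine and NAD metabolism, the pathway that makes AhR ligands from tryptophan, had 6 of 16 members up and 4 down in wild type (camera adjusted p = 0.166) and 4 up and 4 down in AhR-deficient cells (adjusted p = 0.220). Il4i1, which encodes an amino acid oxidase known to yield AhR ligands, rose by 4.93 ± 0.31 in wild type and 4.07 ± 0.34 in AhR-deficient cells, although 85.9% of its exon bases lie under a gene on the opposite strand. Kmo (1.62 ± 0.08 and 1.94 ± 0.10) and Kynu (1.56 ± 0.17 and 1.31 ± 0.19), enzymes of kynurenine breakdown, rose as well. Macrophage genes split, with 6 of 21 up and 7 down in wild type (adjusted p = 0.825). The engulfment receptor gene Mertk rose (4.40 ± 0.20 in wild type, 4.54 ± 0.23 in AhR-deficient cells), while Gpnmb (-2.29 ± 0.13 and -2.17 ± 0.15) and the lipoprotein gene Apoe (-1.61 ± 0.17 in wild type) fell. Of the chemokine receptor and adhesion genes, 3 of 18 rose and 8 fell in wild type (adjusted p = 0.183). Pecam1 (2.74 ± 0.18 and 2.82 ± 0.21) and the neutrophil chemokine receptor gene Cxcr2 (2.64 ± 0.25 and 3.08 ± 0.30) rose, and the fractalkine receptor gene Cx3cr1 (-1.73 ± 0.15 and -1.66 ± 0.17) and the integrin gene Itgal (-0.99 ± 0.09 and -1.05 ± 0.11) fell.

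In the dendritic cell list, 3 of 17 members rose and 7 fell in wild type (adjusted p = 0.237). The growth factor receptor gene Flt3 rose (1.15 ± 0.12 in wild type, 1.28 ± 0.14 in AhR-deficient cells) and the regulator gene Id2 fell (-0.86 ± 0.08 in wild type). Glycolysis genes were not called either (3 of 21 measured members rose, 7 fell and 11 did not pass in wild type, adjusted p = 0.755). The phosphofructokinase gene Pfkp (0.99 ± 0.06 and 0.82 ± 0.07), the lactate transporter gene Slc16a1 (1.66 ± 0.10 and 1.51 ± 0.12) and the hexokinase gene Hk3 (1.20 ± 0.08 and 0.90 ± 0.09) rose, and Pfkfb3, a regulator of the pathway, fell (-1.38 ± 0.08 and -1.15 ± 0.09).

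Prg2, the major basic protein gene of eosinophils, ranged widely within the groups: 98.1, 91.1, 29.7 and 19.9 CPM in wild type in medium (numbers 1, 2, 3 and 7) and 124, 94.2, 21.4 and 40.9 CPM in wild type in IL-4. It stood at 50.7, 19.2 and 9.13 CPM in AhR-deficient cells in medium (numbers 4, 5 and 6) and 43, 19.7 and 9.01 CPM in IL-4. Its genotype differences did not pass (-1.18 ± 0.75 in medium, adjusted p = 0.346; -1.56 ± 0.76 in IL-4, adjusted p = 0.297). The score of neutrophil and eosinophil markers was 3.23 ± 0.57 and 3.28 ± 0.50 (mean log2 CPM ± SD, n = 4) in wild type in medium and IL-4, and 2.56 ± 0.65 and 2.34 ± 0.60 (n = 3) in AhR-deficient cells.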
